A study of Rattus norvegicus with 12 samples.

How the data were processed

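Ventral dentate gyrus, the granule cell region of the hippocampus, was taken from male rats of 2 related lines. The Flinders Sensitive Line (FSL) is a rat line widely used as a model of depression, and the Flinders Resistant Line (FRL) is its control line. Total RNA from about 130 mg of lysed tissue was made into ribosomal-RNA-depleted, stranded libraries and sequenced as 100 bp single reads, per the labels' protocols. The 12 libraries fall into 4 groups of 3: FRL vehicle, FSL vehicle, FSL given L-acetyl-carnitine (LAC) and called non-responders, and FSL given LAC and called responders. LAC, an acetylated form of the fatty acid carrier carnitine, was given in drinking water at 0.3% w/v for 7 days, about 210 mg/kg per day, per the labels. The labels call the libraries of a group biological replicates. How many animals made 1 library, and what separated responders from non-responders, are not given in the sources used here.

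The deposited files hold whole-number read counts per gene symbol, not normalized, for 17172 genes plus 5 summary lines per library. The submitters' processing notes name FastQC 0.11.3, Trimmomatic 0.33, TopHat2 2.0.9, HTSeq 0.6.1, edgeR 3.12.0 and the genome build rn5, without roles or settings. The annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. No genome was used here. A table of RefSeq genes on the assembly GRCr8 served for gene names and for the order of neighbouring genes. In it 16750 of the 17172 symbols were found, and its coordinates were used only to put genes in order.

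Counts in genes summed to 5.91 to 8.14 M (M for mega) per library. Lines for reads outside any gene, ambiguous reads and reads aligned to several places were left out of library sizes and tests; they made up 47.7% to 52.7%, 0.0756% to 0.106% and 24.3% to 28.4% of the reads in the files. Leaving out reads with several alignments lowers genes with close copies, so Cyp2d1, Gstm4, Fcrl2, Rnase4 and the RT1 genes are uncertain. A count of 3 in a library corresponds to 0.369 to 0.508 counts per M counts (CPM), and this floor covers counting error only.

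The main test was edgeR 4.0.16 in R 4.3.3: TMM factors (0.975 to 1.04), the default expression filter on groups, which kept 11750 genes, and a robust quasi-likelihood fit of all 12 libraries with 1 mean per group, two-sided, with Benjamini-Hochberg (BH) adjustment and a threshold of 0.05. The common biological coefficient of variation was 0.178. Fold changes are on the log2 scale with their standard error (SE). Replicate levels are CPM on TMM-scaled library sizes, as mean ± SD with n = 3. Named genes followed a rule set before the data were examined. It took the 10 largest rises and falls past the threshold with a mean of at least 1 CPM and no overlap between groups, up to 15 list members past the threshold, and, where fewer than 10 genes passed, all of these and the 5 genes of smallest p. It also took 10 genes fixed in advance for the line comparison and for responders against non-responders. Members of lists given as examples, and genes of comparisons outside the rule, were chosen after their values were seen.

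The design, the alternatives, 15 gene lists and 18 cell-type marker lists were fixed at that same point. Each list was tested against all other genes with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, BH-adjusted over 165 tests (33 lists in 5 comparisons). The same tests were run with an estimated correlation and with the rotation test fry. List medians are medians of edgeR log2 fold changes. Some lists share genes: Igf2 stands in the insulin and the meningeal list. The GABAergic interneuron list shares 8 of its 15 members in the files with other lists. Among these, Gad1, Gad2, Slc32a1 and Pvalb also stand in GABA and interneurons, so calls of both lists in a comparison are not independent.

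Alternatives covered other scaling, filters, DESeq2 1.42.0, limma-voom, fits of the compared groups only, the replicate number as a block, a choroid plexus covariate, a surrogate variable (sva 3.50.0) that correlated at -0.992 with the meningeal marker mean over the 12 libraries, other thresholds and each library left out. By the rule used here the numbers in the library names pair FSL vehicle with non-responders and no other 2 groups, although the labels name no pairing. All 3 same-number pairs of these groups correlated above 0.1 (0.581, 0.212 and 0.426). The surrogate variable and the meningeal covariate are therefore nearly the same alternative. Alternatives chosen after seeing the data were the mean of all 9 FSL-line libraries against FRL vehicle, a meningeal covariate, 3 marker covariates together, a replicate block in a fit of FSL vehicle and non-responders only, and leaving out the 3 libraries with high choroid plexus markers (FSL vehicle 1 and 3, non-responder 1) or the 2 with low granule neuron markers (FRL vehicle 2, responder 1). Without the 3, FSL vehicle holds 1 library, which the fit assumes to vary like those of the other groups. In simulated counts with known changed genes, 28.4%, 65.7% and 87.9% of genes changed by 1.5, 2 and 4 times were recovered for the line comparison, and 22.4%, 68.7% and 90.9% for responders against FSL vehicle. For non-responders against FSL vehicle these were 16.4%, 61.2% and 92.4%, for responders against non-responders 35.8%, 74.6% and 89.4%, and for pooled LAC 43.3%, 82.1% and 90.9%. Genes were simulated independently, so these shares leave out differences in tissue makeup between libraries. No pair of libraries within a group held near-identical counts (chi-square per degree of freedom 5.35 to 27.1).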

Results

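Gene expression in ventral dentate gyrus was measured by RNA sequencing in 12 libraries, 3 for each of FRL vehicle, FSL vehicle, LAC non-responders and LAC responders. The counts in genes averaged 7.15 ± 1.08 M in FRL vehicle, 6.86 ± 0.706 M in FSL vehicle, 7.43 ± 0.332 M in non-responders and 7.94 ± 0.336 M in responders (mean ± SD, n = 3 each). FRL vehicle 3 was the shallowest library at 5.91 M and responder 2 the deepest at 8.14 M. Between 13183 and 13579 genes had at least 1 count per library.

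Markers of tissue around the dentate gyrus differed widely between libraries. Ttr, which encodes transthyretin, the main secreted protein of the choroid plexus, stood at 2783 CPM in FSL vehicle 1, 289 CPM in FSL vehicle 3 and 5388 CPM in non-responder 1, and at 3.07 to 40.1 CPM in the other 9 libraries. The first principal component of the 12 libraries (36.4% of variance) correlated at 0.979 with the mean of meningeal and fibroblast markers. These markers averaged 7.73 log2 CPM in FSL vehicle 3 and 6.13 in FSL vehicle 2, against 3.07 in responder 2 and 3.10 in responder 3. Prox1, a transcription factor of dentate granule neurons, stood at 10.4 CPM in FRL vehicle 2 and 9.19 CPM in responder 1, and at 51.6 to 129 CPM elsewhere. In responder 1, Tcf7l2 and Slc17a6, both abundant in thalamic neurons, reached 156 and 274 CPM, against at most 20.5 and 69.5 CPM in any other library.

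**Figure D1:**
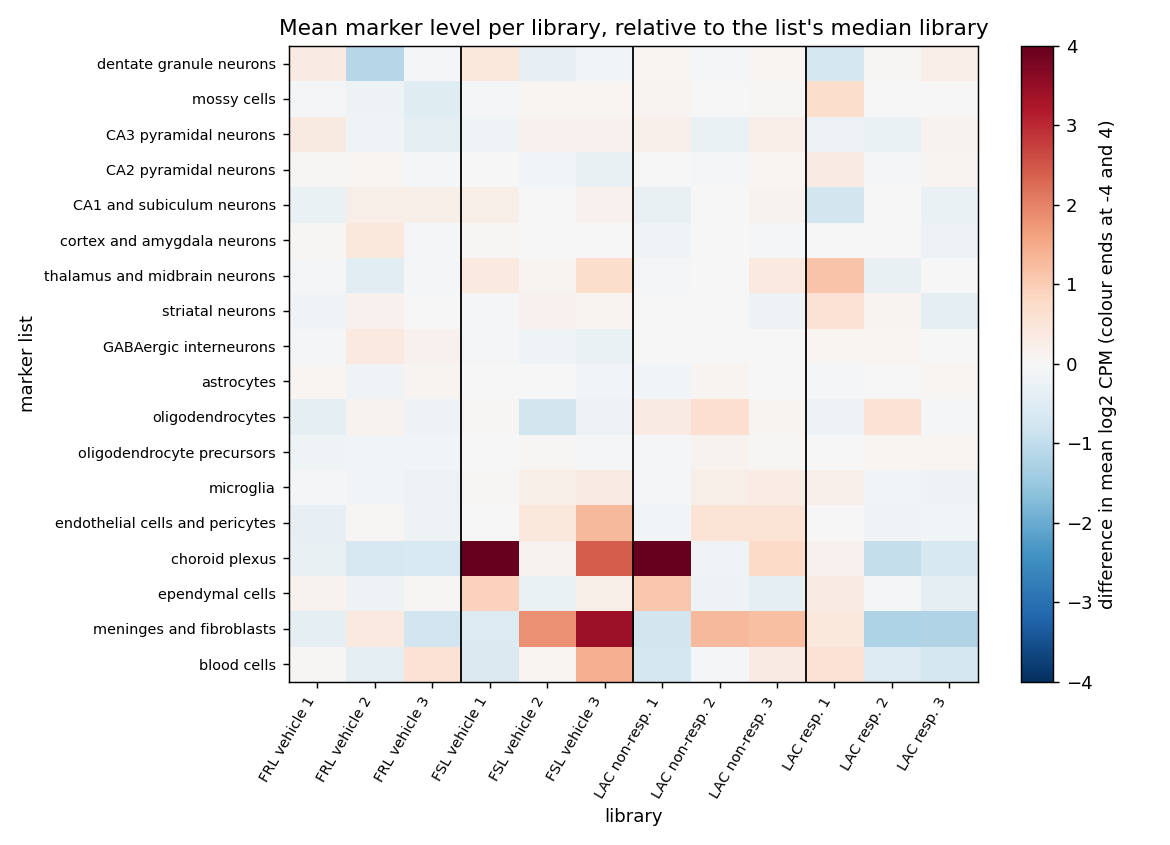
Mean log2 CPM of each of the 18 marker lists in each library, as the difference from that list's median over the 12 libraries; vertical lines part the 4 groups, and colours end at -4 and 4. The choroid plexus list stands out in FSL vehicle 1 (mean 5.71 log2 CPM), FSL vehicle 3 (4.03) and non-responder 1 (6.51), and the meningeal list in FSL vehicle 3 (7.73).

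The first comparison asked how the untreated lines differ. In FSL vehicle, Car3, a carbonic anhydrase abundant in muscle and fat, was 32.3-fold lower than in FRL vehicle (0.636 ± 0.328 against 20.7 ± 5.23 CPM, mean ± SD, n = 3; log2 fold change -5.02 ± 0.43 SE). Rnase4, a secreted ribonuclease, was 7.71-fold lower (8.5 ± 2.53 against 65.2 ± 6.59 CPM; log2 fold change -2.95 ± 0.30). The 6 genes that were higher were Prelp, a matrix proteoglycan of connective tissue (log2 fold change 2.20 ± 0.30), Sgms2, a sphingomyelin synthase (1.88 ± 0.27), and Ghdc (1.87 ± 0.21), with Cmc1, Egf and Mpeg1. Cmc1, a mitochondrial protein, had 1.64 ± 0.23, Egf, epidermal growth factor, 1.47 ± 0.22, and Mpeg1, a pore-forming protein of macrophages and microglia, 1.14 ± 0.14 (49.4 ± 6.31 against 22.4 ± 1.74 CPM). These 8 genes passed an adjusted p of 0.05 among 11750 tested (edgeR quasi-likelihood, BH), with adjusted p from 0.00131 for Car3 to 0.0405 for Egf. In each of them all 3 FSL vehicle libraries lay on 1 side of all 3 FRL vehicle libraries. By the same edgeR test 1631 genes had an unadjusted p under 0.05 (1099 higher, 532 lower), against 588 by chance. That number was 2101, 2569 and 744 without FSL vehicle 1, 2 and 3. It was 724 with a meningeal covariate, 623 with a surrogate variable and 396 with 3 marker covariates.

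Of the 10 genes fixed in advance for their links to stress, glutamate and carnitine metabolism, none passed in this comparison. The glucocorticoid receptor Nr3c1 had a log2 fold change of 0.03 ± 0.12 and the mineralocorticoid receptor Nr3c2 0.17 ± 0.34. The metabotropic glutamate receptor Grm2 had -0.18 ± 0.24, the neurotrophin Bdnf -0.31 ± 0.19 and the insulin receptor Insr 0.05 ± 0.16. The carnitine enzymes Crat and Cpt1a had -0.03 ± 0.09 and 0.22 ± 0.09, the stress peptide Crh -0.04 ± 0.43 and its axis gene Fkbp5 0.21 ± 0.26. Ttr had 6.74 ± 2.44 (1030 ± 1524 against 9.55 ± 6.86 CPM; adjusted p = 0.280), the SD being larger than the FSL mean.

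Camera with a preset correlation called 9 lists in this comparison, 5 higher and 4 lower in FSL vehicle. All 14 meningeal and fibroblast markers had positive log2 fold changes (median 2.49, camera adjusted p = 2.072e-05); 12 passed when adjusted over the list alone, such as Dcn (1.44 ± 0.39) and Igf2 (2.51 ± 0.70), and 0 over all genes. The endothelial and pericyte list had a median of 0.71 (15 of 18 positive, adjusted p = 5.332e-05), with 13 passing when adjusted over the list alone, such as Cldn5 (0.59 ± 0.16) and Acta2 (2.82 ± 0.95), and 0 over all genes. Choroid plexus markers (median 3.89, 19 of 19 positive), the immune and antigen presentation list (0.77, 31 of 32) and microglia (0.32, 15 of 15) had 0 members passing on either scale. All 49 oxidative phosphorylation genes had negative values (median -0.10), as had 32 of 35 of glycolysis and the citrate cycle (-0.17) and 23 of 29 GABA and interneuron genes (-0.15). Of 11 GABAergic interneuron markers (median -0.28), Lamp5 (-0.90 ± 0.18), Slc32a1 (-0.48 ± 0.13) and Pvalb (-0.58 ± 0.20) passed when adjusted over the list alone, and 0 over all genes. None of the 9 lists was called with an estimated correlation (adjusted p = 0.801 for oxidative phosphorylation and 0.746 for the other 8) or by fry.

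Lists that camera did not call in this comparison included carnitine and fatty acid oxidation (median log2 fold change 0.06, adjusted p = 0.509), glutamate receptors and transport (-0.08), insulin and glucose signalling (0.08), cholinergic and monoamine receptors (-0.05) and oxidative stress and xenobiotic enzymes (0.04). In the last of these, Ephx2 (-1.79 ± 0.36), Ephx1 (1.30 ± 0.27), Gsta4 (0.66 ± 0.18), Sod3 (1.3 ± 0.34) and Gpx1 (0.64 ± 0.19) passed when adjusted over the list alone, and 0 over all genes. Medians were 0.02 for chromatin acetylation and methylation, 6.15e-04 for the stress hormone axis, -0.03 for growth factors and neurogenesis, -0.05 for the circadian clock and -0.08 for immediate early genes, and in these 5 lists the median, mean and test did not share 1 sign. Ribosomal proteins (0.02), dentate granule neurons (0.16), mossy cells (0.16), CA2 (-0.11), CA1 and subiculum (0.10), cortex and amygdala (-0.21), thalamus and midbrain (0.77) and striatal neurons (8.97e-04) were not called. In the thalamus list Zic1 (1.87 ± 0.43) and Prkcd (0.78 ± 0.24) passed when adjusted over the list alone, and 0 over all genes. Astrocytes (-0.05), oligodendrocytes (-0.29), their precursors (0.13), ependymal cells (0.05) and blood cells (0.18) were not called either. CA3 had -0.17, and its mean and median differed in sign.

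The line count rested on few libraries: 271 genes (250 higher, 21 lower) passed without FSL vehicle 1, against 3, 2 and 5 without FRL vehicle 1, 2 and 3. Car3 and Rnase4 passed with each of the 6 libraries left out, while Ghdc did so in 5, Prelp and Mpeg1 in 3, Sgms2 and Egf in 2 and Cmc1 in 1. DESeq2 called 168 genes. With a choroid plexus covariate 0 passed (smallest adjusted p = 0.0927), although the 8 genes kept 0.891 to 1.02 times their fold change, such as Car3 at -5.12 ± 0.63 and Ghdc at 1.78 ± 0.26. Their median SE rose from 0.25 to 0.30 and the residual degrees of freedom fell from 8 to 7. Prelp fell to 1.13 and Sgms2 to 1.19 with 3 marker covariates. Without FSL vehicle 3 camera no longer called oxidative phosphorylation (median on log2 CPM -0.0062, adjusted p = 0.587) or GABA and interneurons (-0.08, 0.216). With 3 marker covariates oxidative phosphorylation was called in the opposite direction (0.19, adjusted p = 1.37e-06), and the medians of the immune list (-0.17, adjusted p = 0.167) and glycolysis (0.06, 0.619) turned and were not called.

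**Figure D2:**
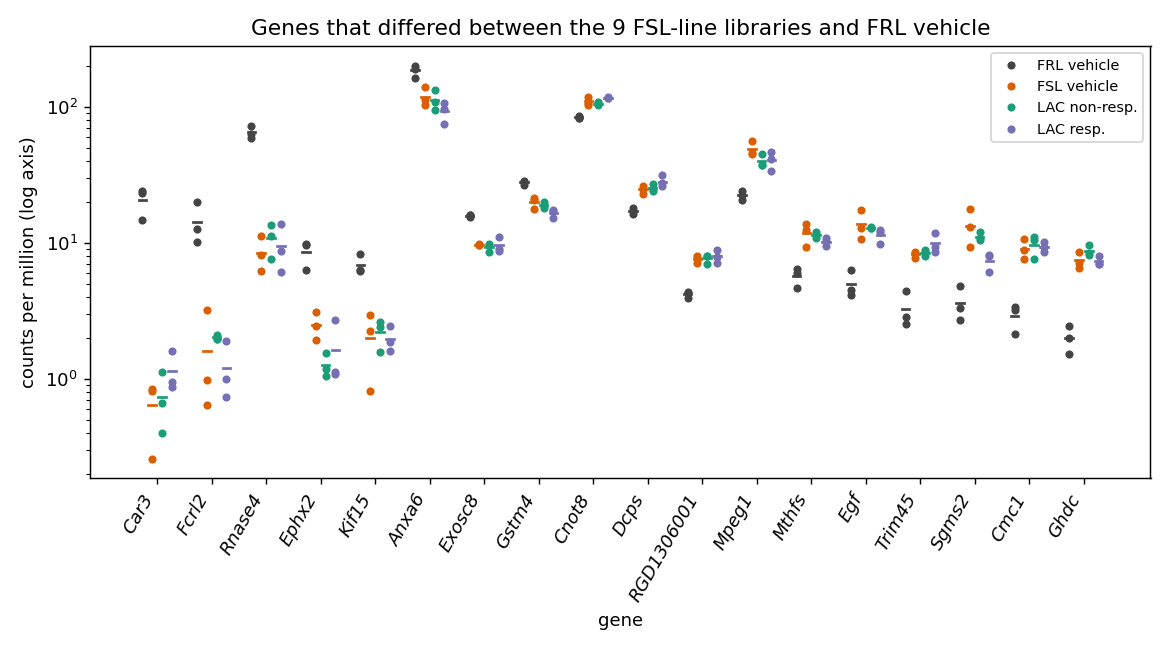
CPM on a log axis in each library for 18 of the 19 genes that differed between the 9 FSL-line libraries and FRL vehicle; points are libraries, bars are group means (n = 3), and Cyp2d1 is left out because it had no counts in FRL vehicle. In each gene the FRL vehicle libraries lie apart from all FSL-line libraries, as for Rnase4 (59.9 to 72.6 against 6.07 to 13.8 CPM).

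Responders were compared with FSL vehicle to ask what accompanies a response to LAC. No gene passed (edgeR quasi-likelihood, BH; smallest adjusted p = 0.237), while 1619 genes had an unadjusted p under 0.05 (542 higher, 1077 lower), against 588 by chance. That number was 637 without FSL vehicle 3 and 2986 without FSL vehicle 2, and 917 in the compared groups only, 670 with a meningeal covariate, 583 with a surrogate variable (which correlated at -0.992 with the meningeal mean) and 453 with 3 marker covariates. DESeq2 called 186 genes and limma-voom 0. The 5 genes of smallest p, none past the threshold, were Tcn2, Sept9, Vamp1, Capn6 and Cabp1, each with adjusted p = 0.237 and no overlap between the groups. Tcn2, a vitamin B12 carrier, had a log2 fold change of -1.02 ± 0.16 (22.5 ± 3.87 against 45.5 ± 9.77 CPM), Sept9 -0.42 ± 0.07 and Capn6 -1.43 ± 0.25. Vamp1, a synaptic vesicle fusion protein, had 0.64 ± 0.11 and Cabp1, a neuronal calcium-binding protein, 0.62 ± 0.11. Over all tested genes, 12.5% had groups that did not overlap, where chance gives 10%.

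By the preset-correlation test 12 lists were shifted. Meningeal and fibroblast markers had a median log2 fold change of -2.67 (14 of 14 negative, camera adjusted p = 2.138e-07). Of these, 13 members passed when adjusted over the list alone, such as Dcn (-2.06 ± 0.40) and Col1a1 (-3.08 ± 0.98), and 0 over all genes. The immune and antigen presentation list had -0.86 (31 of 32 negative, adjusted p = 6.212e-09). Here 12 members passed when adjusted over the list alone, among them B2m (-0.59 ± 0.15), Cd74 (-3.34 ± 1.02) and the complement gene C4b (-3.43 ± 1.12), and 0 over all genes. In the insulin and glucose list (median -0.17) the members that passed over the list alone were Igf2 (-3.55 ± 0.73), a growth factor that the meningeal list also holds, and its binding protein Igfbp2 (-3.33 ± 0.75). Choroid plexus (-4.22), endothelial cells and pericytes (-0.59; 8 lower and 1 higher over the list alone) and microglia (-0.22) were also lower. Oxidative phosphorylation (0.15, 46 of 49 positive), glycolysis and the citrate cycle (0.14), GABA and interneurons (0.20) and GABAergic interneurons (0.27) were higher, and Lamp5 (0.89 ± 0.17) and Gad2 (0.35 ± 0.10) passed over the list alone. Oligodendrocytes (0.58) and ribosomal proteins (0.06) were also higher, and 0 members of these lists passed over all genes. None was called with an estimated correlation (adjusted p = 0.926 for ribosomal proteins and 0.746 for the other 11).

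The meningeal markers averaged 3.76, 6.13 and 7.73 log2 CPM in FSL vehicle 1, 2 and 3, and 4.75, 3.07 and 3.10 in responders. Without FSL vehicle 1, which had the lowest meningeal level of its group, 349 genes passed (16 higher, 333 lower). With 3 marker covariates oxidative phosphorylation was called lower (median on log2 CPM -0.17, adjusted p = 1.59e-05). The immune list then turned to 0.17 (adjusted p = 0.447), endothelial cells to 0.11, glycolysis to -0.09 and insulin to 0.03, none of them called. Without FSL vehicle 3 camera no longer called oxidative phosphorylation (median on log2 CPM 0.05, adjusted p = 0.0561), glycolysis and the citrate cycle (0.05), insulin and glucose signalling (-0.06) or GABA and interneurons (0.13; 0.09 without responder 1). The oligodendrocyte call ended without FSL vehicle 2 (0.40) or responder 2 (0.33), and that of microglia without FSL vehicle 2 (-0.16), responder 2 (-0.18) or responder 3 (-0.11). The call ended for ribosomal proteins without FSL vehicle 1 (0.0015), responder 1 (0.02) or responder 2 (0.05), and for GABAergic interneurons without any of FSL vehicle 2 and 3 (0.16, 0.13) and responder 1, 2 and 3 (0.15, 0.26, 0.25).

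**Figure D3:**
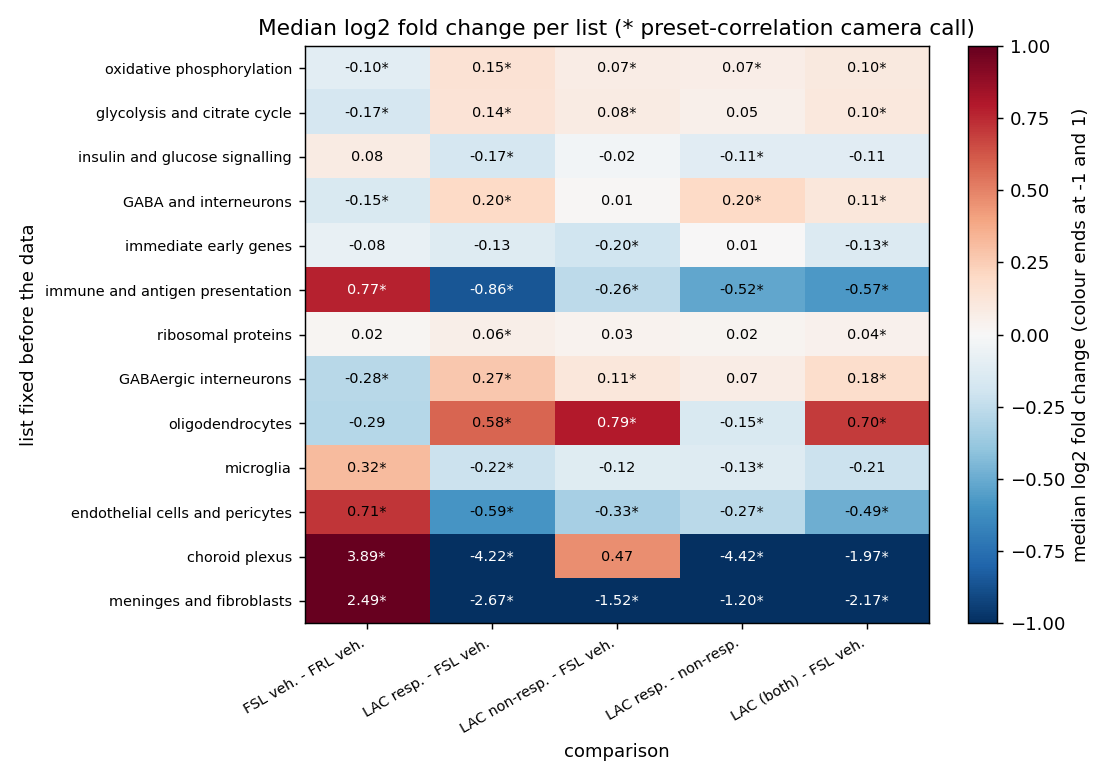
Median log2 fold change of the 13 lists called in at least 1 of 5 comparisons, with the comparison on the horizontal axis; an asterisk marks a call by camera with a preset correlation, and colours end at -1 and 1. The immune list goes from 0.77 in FSL vehicle against FRL vehicle to -0.86 in responders against FSL vehicle, comparisons that share the FSL vehicle libraries; 0 calls held with an estimated correlation.

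Non-responders were compared with FSL vehicle to ask what LAC accompanies where no response was seen. No gene passed (edgeR quasi-likelihood, BH; smallest adjusted p = 0.976). Among tested genes 495 had an unadjusted p under 0.05, against 588 by chance, and DESeq2 called 2 genes and limma-voom 0. The 495 became 1188, 1161 and 320 without FSL vehicle 1, 2 and 3, and 327 with a surrogate variable. The 5 genes of smallest p, none past the threshold, were Capn6 (log2 fold change -1.47 ± 0.25), Eepd1 (0.57 ± 0.11), the glucocorticoid-induced kinase Sgk1 (0.68 ± 0.14; 294 ± 17.7 against 184 ± 8.68 CPM), Fam98a (0.33 ± 0.07) and Vamp1 (0.51 ± 0.11). Groups did not overlap in 7.80% of genes, where chance gives 10%.

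Oligodendrocyte markers were shifted upward by the preset-correlation test (median log2 fold change 0.79, 14 of 15 positive, camera adjusted p = 1.712e-10). Of these, 11 passed when adjusted over the list alone, such as the myelin genes Mbp (0.89 ± 0.29; 3479 ± 1098 against 1879 ± 439 CPM) and Mog (0.79 ± 0.29), and 0 over all genes. Meningeal and fibroblast markers (-1.52, 14 of 14 negative), endothelial cells and pericytes (-0.33), the immune list (-0.26) and immediate early genes (-0.20, 27 of 36 negative) were lower, with 0 members passing on either scale. Oxidative phosphorylation (0.07), glycolysis and the citrate cycle (0.08) and GABAergic interneurons (0.11; Lamp5 0.80 ± 0.18 over the list alone) were higher, with 0 members passing over all genes. With an estimated correlation none of the 8 was called (adjusted p = 0.746 to 0.849, among them 0.746 for oligodendrocytes). Without FSL vehicle 3 the medians on log2 CPM turned for oxidative phosphorylation (-0.0096), the immune list (0.07) and the endothelial list (0.05). The calls of meningeal markers (-0.03), glycolysis (0.02), GABAergic interneurons (0.15) and immediate early genes (-0.18) ended there too, so that only oligodendrocytes stayed called. The immune list turned to 0.11 (adjusted p = 0.206) and oxidative phosphorylation to -0.02 (0.603) with 3 marker covariates. Calls also ended without FSL vehicle 2 for meningeal markers (-0.81), the immune list (-0.28), immediate early genes (-0.12) and GABAergic interneurons (0.12). Without non-responder 1 they ended for meningeal markers (-0.36), the immune list (-0.02), oxidative phosphorylation (0.04) and the endothelial list (-0.10), and without non-responder 3 for immediate early genes (-0.13).

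The comparison of responders with non-responders also tests whether the differences of the 2 LAC groups from FSL vehicle are unlike. FSL vehicle was not divided by response, so a difference between animals before treatment cannot be told from an effect of LAC. No gene passed (edgeR quasi-likelihood, BH; smallest adjusted p = 0.992). Among tested genes 369 had an unadjusted p under 0.05, against 588 by chance, and DESeq2 and limma-voom called 0. It was 612 genes in the compared groups only, 1013 without the 3 libraries high in choroid plexus markers and 236 without the 2 low in granule neuron markers. The 5 genes of smallest p, none past the threshold, were Pmch, C1qtnf3, Clybl, Vamp8 and Ptger3. Pmch, a hypothalamic peptide gene, had a log2 fold change of 5.32 ± 1.27 (4.23 ± 4.67 against 0.0879 ± 0.0762 CPM, the latter under the floor of 3 counts). Pmch was highest in responder 1 (9.43, 2.85 and 0.405 CPM in responder 1, 2 and 3), and its log2 fold change was 3.96 without that library. C1qtnf3 (-2.70 ± 0.66) stood at 15.2, 2.64 and 2.97 CPM in non-responder 1, 2 and 3, and had -1.41 without non-responder 1, the library highest in choroid plexus markers. The others were Clybl (-0.72 ± 0.18; 8.20 ± 0.411 against 13.5 ± 0.215 CPM), Vamp8 (-0.74 ± 0.19) and Ptger3, a prostaglandin receptor (1.14 ± 0.31). Grm2 (-0.18 ± 0.24), Nr3c1 (-0.13 ± 0.12), Nr3c2 (-0.14 ± 0.34), Bdnf (-0.06 ± 0.19), Insr (-0.11 ± 0.16), Crat (0.01 ± 0.09), Cpt1a (-0.14 ± 0.09), Crh (0.06 ± 0.42), Fkbp5 (-0.17 ± 0.26) and Ttr (-6.55 ± 2.37, but -0.31 without non-responder 1) did not pass either.

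In this comparison 9 lists were shifted by the preset-correlation test, and 0 of their members passed over all genes. Choroid plexus markers had a median log2 fold change of -4.42 (19 of 19 negative, camera adjusted p = 1.212e-09), with 16 passing when adjusted over the list alone. Their mean levels were 6.51, 1.47 and 2.38 log2 CPM in non-responder 1, 2 and 3 and 1.78, 0.67 and 0.98 in responder 1, 2 and 3. Meningeal and fibroblast markers (-1.20), the immune list (-0.52, 31 of 32 negative), endothelial cells and pericytes (-0.27), oligodendrocytes (-0.15), microglia (-0.13) and insulin and glucose signalling (-0.11) were lower in responders. GABA and interneurons (0.20, 26 of 29 positive) and oxidative phosphorylation (0.07, 44 of 49 positive) were higher. With an estimated correlation the adjusted p was 0.849 for oxidative phosphorylation and oligodendrocytes and 0.746 for the other 7. The carnitine and fatty acid oxidation list, the pathway of the compound given, had a median of -0.04 (adjusted p = 0.167). On log2 CPM the oligodendrocyte call ended without non-responder 2 (0.04), responder 1 (0.04) or responder 3 (-0.13), oxidative phosphorylation without non-responder 3 (0.03), and GABA and interneurons without responder 1 (0.05). The microglia call ended without non-responder 2 and 3 (-0.09, -0.03) or responder 2 and 3 (-0.14, -0.05), and the endothelial call without the same libraries (-0.21, -0.19, -0.27, -0.26). With the 3 libraries high in choroid plexus markers left out 11 genes passed, all lower in responders. Of these 3 only non-responder 1 is in this comparison, and without it alone 0 genes passed (edgeR quasi-likelihood, smallest adjusted p = 0.958). FSL vehicle 1 and 3 enter only through the shared fit, so the 11 depend on libraries outside the comparison. Meningeal markers averaged 5.62 and 5.52 log2 CPM in non-responder 2 and 3, against 4.75, 3.07 and 3.10 in responder 1, 2 and 3. Oxidative phosphorylation was called lower in responders with 3 marker covariates (-0.16, adjusted p = 1.37e-06), while the immune list turned to 0.10 (0.922) and the endothelial list to 0.06 (0.896) and lost their calls.

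Pooled over response, the 6 LAC libraries were compared with FSL vehicle. No gene passed (edgeR quasi-likelihood, BH; smallest adjusted p = 0.206), while 1374 genes had an unadjusted p under 0.05 (458 higher, 916 lower), against 588 by chance. The 1374 became 459 without FSL vehicle 3, 2622 without FSL vehicle 2, 553 with a meningeal covariate, 485 with a surrogate variable and 427 with 3 marker covariates. DESeq2 called 61 and limma-voom 0. Of 11 lists shifted by the preset-correlation test, meningeal and fibroblast markers (median log2 fold change -2.17; 14 of 14 over the list alone, such as Igf2 at -2.39 ± 0.55) and the immune list (-0.57; 6 over the list alone) were lower. So were choroid plexus (-1.97), endothelial cells and pericytes (-0.49) and immediate early genes (-0.13; Klf2 -1.32 ± 0.33 and Klf4 -1.31 ± 0.34 over the list alone). Oligodendrocytes (0.70; 10 over the list alone, such as Mal at 0.90 ± 0.25) and GABAergic interneurons (0.18; Lamp5 0.85 ± 0.16 over the list alone) were higher. So were GABA and interneurons (0.11), glycolysis (0.10), oxidative phosphorylation (0.10) and ribosomal proteins (0.04), and 0 members of any list passed over all genes. With an estimated correlation none was called (adjusted p = 0.926 for ribosomal proteins, 0.770 for oxidative phosphorylation and 0.746 for the other 9). Without FSL vehicle 1, 323 genes passed (18 higher, 305 lower), the ribosomal median on log2 CPM became -0.01, and choroid plexus was no longer called (-0.20), its median of edgeR fold changes being 0.29. Oxidative phosphorylation was called lower with 3 marker covariates (-0.09, adjusted p = 6.99e-04), and the immune list (0.15, 0.275), the endothelial list (0.05, 0.989) and glycolysis (-0.03, 0.727) turned and were not called. Without FSL vehicle 3 the calls of oxidative phosphorylation (0.02), glycolysis (0.03), GABA and interneurons (0.02), GABAergic interneurons (0.15), the immune list (-0.16) and the endothelial list (-0.10) ended. Without FSL vehicle 2 those of GABA and interneurons (0.13), GABAergic interneurons (0.12) and immediate early genes (-0.14) ended. The immediate early gene call also ended without non-responder 3 (-0.13), responder 1 (-0.13) or responder 3 (-0.13). The call of GABA and interneurons ended without responder 1 (0.08), and that of ribosomal proteins without non-responder 2 (0.01), responder 1 (0.02) or responder 2 (0.04).

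Treated animals were also set against FRL vehicle, to ask which line differences are seen under LAC. In responders 10 genes passed (edgeR quasi-likelihood, BH): Car3 (log2 fold change -4.16 ± 0.39), Rnase4 (-2.77 ± 0.30), Fcrl2 (-3.57 ± 0.52), Ephx2, a soluble epoxide hydrolase (-2.39 ± 0.37), and Gstm4 (-0.75 ± 0.10) were lower. Ghdc (1.87 ± 0.21), Cmc1 (1.68 ± 0.23), Trim45 (1.62 ± 0.22), the mRNA decapping scavenger Dcps (0.72 ± 0.10) and Cnot8 (0.47 ± 0.07) were higher. In non-responders 5 passed: Car3 (-4.81 ± 0.42), Rnase4 (-2.59 ± 0.30), Ephx2 (-2.76 ± 0.38), Ghdc (2.12 ± 0.21) and Cmc1 (1.74 ± 0.23). Car3, Rnase4, Ghdc and Cmc1 passed in FSL vehicle and in both treated groups with the same sign, 4 genes in each pairing. Independent lists would share 0.00255 higher and 8.511e-04 lower genes for responders, and 0.00102 and 5.106e-04 for non-responders. Simulated unchanged groups shared 0, but groups with no changed gene leave few or no calls to share, so this gives no baseline. The real comparisons use the same FRL vehicle libraries, too few to split, so part of the excess over independent lists may come from the shared controls. Across all genes, which are not independent replicates, line fold changes correlated at 0.251 with those of responders (simulated 0.505) and at 0.791 with those of non-responders (simulated 0.507). The counts fell to 3, 2 and 5 for responders without FRL vehicle 1, 2 and 3, and to 4, 0 and 3 without responder 1, 2 and 3. For non-responders they fell to 2 and 3 without FRL vehicle 1 and 2 and to 2 without non-responder 1 or 2.

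Fold changes of the line comparison and of responders against FSL vehicle, which share FSL vehicle with opposite sign, correlated at -0.846 across 11750 genes, which are not independent replicates (simulated unchanged groups gave -0.502). The covariance was -0.237, against -0.0461 in simulated groups. Responder and non-responder fold changes against FSL vehicle correlated at 0.675 (simulated 0.505; covariance 0.116 against 0.0462) and shared 0 called genes, since neither comparison called any by edgeR; DESeq2 calls shared 1. Line fold changes and those of responders against non-responders, which share no library, correlated at -0.630. Simulated unchanged groups gave -0.00653, which leaves out that like-numbered FSL vehicle and non-responder libraries varied together and that genes move together. Over 20 labellings of the LAC libraries as responders or non-responders, the real labels gave -0.613 and the lowest other -0.492. The labellings hold each split and its mirror image, so the highest, 0.613, is the real split with its labels swapped. The lowest other value was itself far from the simulated one.

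**Figure D4:**
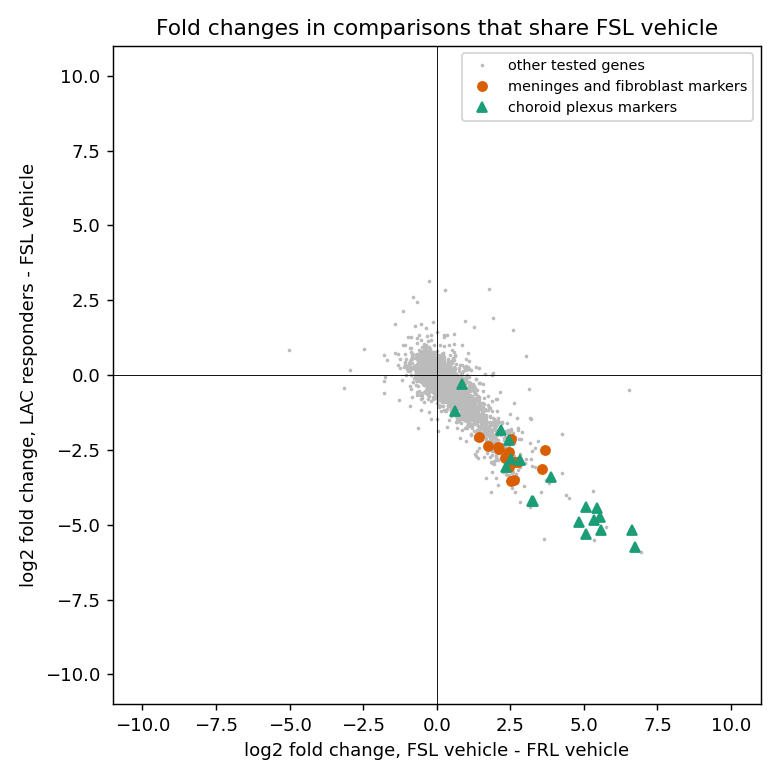
Log2 fold change of each tested gene in FSL vehicle against FRL vehicle (horizontal) and in responders against FSL vehicle (vertical), with meningeal and choroid plexus markers marked. The markers lie at the lower right, with medians of 2.49 and 3.89 in the line comparison and -2.67 and -4.22 in responders; the comparisons share the FSL vehicle libraries.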

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

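The tests of choroid plexus markers in this part, and the alternatives that leave out several libraries, were chosen after the result was seen. The direct comparison of responders with non-responders tests whether the shifts of the 2 LAC groups against FSL vehicle are unlike. In it 9 gene lists passed an adjusted p of 0.05 by camera with a preset correlation. The immune and antigen presentation list had a median log2 difference of -0.52, as 31 of 32 genes lay lower in responders, but with 3 marker covariates, also chosen after the result was seen, it turned to 0.10 (adjusted p = 0.922). Meningeal and fibroblast markers had -1.20, choroid plexus -4.42, endothelial cells and pericytes -0.27, oligodendrocytes -0.15, microglia -0.13 and insulin and glucose signalling -0.11. Genes of GABA and interneurons had 0.20 and oxidative phosphorylation 0.0654 (-0.16 with 3 marker covariates, adjusted p = 1.37e-06). None of the 9 passed with an estimated correlation (smallest adjusted p = 0.746). Taking the 33 lists of this comparison alone, the real grouping called 7 lists and the highest of the other groupings 9; 5 of 10 groupings called at least 7, and 10 are too few to decide.

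Choroid plexus markers were high in FSL vehicle 1 (mean 5.71 log2 CPM), FSL vehicle 3 (4.03) and non-responder 1 (6.51), and at most 2.38 in the other libraries. Choroid plexus tissue carried into these 3 libraries would keep a fixed ratio to Ttr for markers with no other source. The SD of the log2 ratio over the 3 had a median of 0.667. It was small for some markers, such as Folr1 (0.161), Tmem72 (0.199) and Kl (0.278), and large for others, such as Kcnj13 (1.67) and Steap1 (1.64). Slc13a4 (3.11) and Calml4 (1.41) reached 52.5 and 10.9 CPM in other libraries, so no fixed ratio is predicted for them. In all 3, 15 of 19 markers lay above every other library. The median thus mixes unlike markers and decides nothing. A property of the FSL vehicle group would put all 3 of its libraries above FRL vehicle, and the lowest lay 0.455 log2 CPM above the highest FRL vehicle library, but the highest library of all was a non-responder. The high values followed single libraries: FSL vehicle 2 averaged 1.76 log2 CPM and non-responder 2 and 3 averaged 1.47 and 2.38, near responder 1 at 1.78. That argues against a property shared by a whole group as the cause of the high values in these 3 libraries. Whether tissue was carried over stays open, since the ratios differed between markers and dissections are not described in the sources used here. A smaller difference between groups cannot be told with 3 libraries per group.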

How the results depend on the processing

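The alternatives with a meningeal covariate, 3 marker covariates, all 9 FSL-line libraries, or several libraries left out were chosen after seeing the data. Car3, Rnase4, Ghdc, Prelp, Sgms2, Cmc1, Egf and Mpeg1 kept their direction in the line comparison under every setting, with ranges of -6.23 to -4.62 for Car3, -3.39 to -2.76 for Rnase4, 1.13 to 2.39 for Prelp, 1.19 to 2.14 for Sgms2 and 0.67 to 1.20 for Mpeg1, and Car3 and Rnase4 passed the threshold in 18 of 20 settings. Over the named genes, 713 values kept their direction and side of the threshold, 71 fell short of it, 13 came to pass it and 67 turned; for called lists 517 kept both, 217 fell short and 42 turned. The groups hold 3 libraries and 5.91 to 8.14 M gene counts, which limits what can be seen of genes at a few CPM. The cause of the changes below was not tested, except that leaving out libraries or adding covariates leaves fewer degrees of freedom, and that a covariate made of a marker list removes the shift of that list by construction. Leaving out the 3 libraries high in choroid plexus markers leaves FSL vehicle 2 as the only FSL vehicle library. Each comparison with FSL vehicle then sets a single library against a group, on the assumption that it varies like the other groups, so its counts and calls below show no property of FSL vehicle. For responders against non-responders, only non-responder 1 of the 3 is in the comparison, and 0 genes passed without it alone.

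Against 8 genes in the line comparison, DESeq2 called 168 (127 higher, 41 lower), limma-voom 5, a fit of the compared groups only 2, a choroid plexus covariate 0, a surrogate variable 3, a meningeal covariate 4 and 3 marker covariates 0. Leaving out the 3 libraries high in choroid plexus markers gave 17 from 1 FSL vehicle library, the 2 libraries low in granule neuron markers 2, an adjusted p under 0.10 gave 21, and all 9 FSL-line libraries gave 19. Against 0 genes, DESeq2 called 186 (25 higher, 161 lower) for responders, 2 for non-responders and 61 (23 higher, 38 lower) for pooled LAC. Leaving out the libraries high in choroid plexus markers gave 36 for responders and 1 for pooled LAC, both against FSL vehicle 2 alone, and 11 for responders against non-responders, and leaving out those low in granule neuron markers gave 1 for pooled LAC. For responders against FRL vehicle, 10 became 25 by DESeq2, 1 in the compared groups only, 3 with a choroid plexus covariate, 4 and 2 with these libraries left out, and 16 at an adjusted p under 0.10. For non-responders against FRL vehicle, 5 became 28 by DESeq2, 9 in the compared groups only, 2 with a choroid plexus covariate, 0 with 3 marker covariates, 22 and 2 with these libraries left out, and 11 at an adjusted p under 0.10. Genes shared with the line comparison, 4 each, became 18 for responders and 26 for non-responders by DESeq2 and 10 each at an adjusted p under 0.10; responders and non-responders against FSL vehicle shared 1 by DESeq2. The 49 list calls became 0 with an estimated correlation, 0 by fry and 25 with 3 marker covariates, of which 4 are among the 49. Leaving out the libraries high in choroid plexus markers gave 35, of which 23 are among the 49, with 1 FSL vehicle library in 4 of the 5 comparisons.

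With the replicate number as a block, 4 genes passed in the line comparison, 3 for responders and 2 for non-responders against FRL vehicle, and non-responders shared 2 with the line comparison; the list calls came to 47. Over all groups 7 of 18 same-number pairs correlated above 0.1 (-0.338 to 0.581), and 5 of 12 libraries correlated best with their own number. FSL vehicle and non-responders are paired by that bound, and a block in a fit of these 2 groups, chosen after seeing the data, gave 0 genes and kept all 8 list calls of that comparison, so it changed no call there.

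With 1 library left out the count of genes ranged from 2 to 271 in the line comparison, 0 to 349 for responders, and 0 to 323 for pooled LAC. It ranged from 0 to 5 for responders against FRL vehicle and 2 to 6 for non-responders against FRL vehicle, and list calls from 30 to 54. The 271, 349 and 323 came without FSL vehicle 1.

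In the same way log2 fold changes turned for Nr3c1 from -0.014 to 0.12, Nr3c2 from -0.093 to 0.56, Insr from -0.084 to 0.24, Crat from -0.096 to 0.050, Crh from -0.39 to 0.33 in the line comparison. They turned for Grm2 from -0.46 to 0.097, Nr3c2 from -0.48 to 0.13, Bdnf from -0.18 to 0.12, Crat from -0.022 to 0.032, Crh from -0.18 to 0.31, Fkbp5 from -0.33 to 0.033 in responders against non-responders. List medians turned for ribosomal proteins in pooled LAC (-0.010 to 0.098), for oligodendrocytes in responders against non-responders (-0.45 to 0.042), and in non-responders for oxidative phosphorylation (-0.0096 to 0.18), the immune list (-0.40 to 0.075) and the endothelial list (-0.51 to 0.047).

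None of the genes that turned under other settings passed the threshold in either. With library size only, Crat had 0.020 and Crh 0.012 for FSL vehicle against FRL vehicle. By limma-voom, Crh had 0.10 for FSL vehicle against FRL vehicle. With a choroid plexus covariate, Nr3c2 had -0.024, Insr -0.086 and Ttr -0.15 for FSL vehicle against FRL vehicle. Nr3c2 had 0.037, Bdnf 0.025 and Ttr 1.30 for responders against non-responders. With a surrogate variable, Grm2 had 0.11, Nr3c1 -0.040, Insr -0.023, Crat 0.070 and Fkbp5 -0.20 for FSL vehicle against FRL vehicle. Crat had -0.048 and Fkbp5 0.068 for responders against non-responders. With a meningeal covariate, Grm2 had 0.081, Nr3c1 -0.027, Crat 0.046 and Fkbp5 -0.13 for FSL vehicle against FRL vehicle. Crat had -0.042 and Fkbp5 0.059 for responders against non-responders. With 3 marker covariates, Grm2 had 0.49, Bdnf 0.091, Insr -0.43, Crat 0.075, Crh 0.26, Fkbp5 -0.30 and Ttr -0.34 for FSL vehicle against FRL vehicle. Insr had 0.23, Crat -0.063, Cpt1a 0.0093, Crh -0.042, Fkbp5 0.15 and Ttr 1.5 for responders against non-responders. Without the 3 libraries high in choroid plexus markers, Nr3c1 had -0.030, Bdnf 0.0093, Insr -0.41 and Crat 0.0085 for FSL vehicle against FRL vehicle. Bdnf had 0.12 for responders against non-responders. Without the 2 libraries low in granule neuron markers, Nr3c2 had -0.093 and Crh 0.33 for FSL vehicle against FRL vehicle. Grm2 had 0.098, Nr3c2 0.13, Bdnf 0.043 and Crh -0.18 for responders against non-responders.

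For lists, the medians here are of differences in log2 CPM, so they differ slightly from those of edgeR fold changes in the report, and the median or the direction of the test turned. Of the lists that turned, only oxidative phosphorylation was then called. With 3 marker covariates this was so in the line comparison (adjusted p = 1.37e-06), responders (1.59e-05), responders against non-responders (1.37e-06) and pooled LAC (6.99e-04). Without the libraries high in choroid plexus markers it passed in the line comparison (0.0167), non-responders (4.99e-08) and pooled LAC (1.15e-04), but each of these rests on FSL vehicle 2 alone and is not read as a reversal. With a choroid plexus covariate, choroid plexus had -0.30 for FSL vehicle against FRL vehicle. Ribosomal proteins had -6.91e-05 and choroid plexus 0.59 for responders against FSL vehicle. Choroid plexus had 0.15 for responders against non-responders. Choroid plexus had 0.31 for pooled LAC. With 3 marker covariates, oxidative phosphorylation had 0.19, glycolysis 0.063, immune -0.17, choroid plexus -0.13 and meninges -0.13 for FSL vehicle against FRL vehicle. Oxidative phosphorylation had -0.17, glycolysis -0.092, insulin 0.033, immune 0.17, GABAergic interneurons 0.037, endothelial 0.11 and choroid plexus 0.041 for responders against FSL vehicle. Oxidative phosphorylation had -0.016, immune 0.11 and meninges -0.089 for non-responders against FSL vehicle. Oxidative phosphorylation had -0.16, immune 0.10 and endothelial 0.059 for responders against non-responders. Oxidative phosphorylation had -0.091, glycolysis -0.033, immune 0.15, endothelial 0.051 and choroid plexus 0.19 for pooled LAC. Without the 3 libraries high in choroid plexus markers, oxidative phosphorylation had 0.085 for FSL vehicle against FRL vehicle. Oxidative phosphorylation had -0.056 and ribosomal proteins -0.057 for responders against FSL vehicle. Oxidative phosphorylation had -0.15, glycolysis -0.090 and endothelial -0.016 for non-responders against FSL vehicle. Oxidative phosphorylation had -0.10, glycolysis -0.035 and ribosomal proteins -0.045 for pooled LAC.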

Other observations

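The comparison of all 9 FSL-line libraries with FRL vehicle, the test of like-numbered libraries, and the tests of other tissue and of a strain variant were chosen after the result was seen. So were the genes and markers named in this part. Between the 9 FSL-line libraries, treated or not, and the 3 FRL vehicle libraries, 19 genes passed (edgeR quasi-likelihood, BH; 11 higher, 8 lower), and in all 19 the lines did not overlap. Besides Car3 (log2 fold change -4.66 ± 0.27 SE) and Rnase4 (-2.77 ± 0.21), lower genes were Fcrl2 (-3.17 ± 0.35; 1.61 ± 0.842 against 14.3 ± 5.13 CPM, mean ± SD, n = 9 and 3) and the epoxide hydrolase Ephx2 (-2.31 ± 0.27; 1.79 ± 0.778 against 8.60 ± 2.0 CPM). The mitotic motor Kif15 (-1.74 ± 0.28), Anxa6 (-0.79 ± 0.13), Exosc8 of the RNA exosome (-0.73 ± 0.10) and Gstm4 (-0.60 ± 0.08) were also lower. Higher genes were Ghdc (1.95 ± 0.19), Cmc1 (1.69 ± 0.20), Sgms2 (1.5 ± 0.24), Trim45 (1.45 ± 0.19) and Egf (1.36 ± 0.19), together with Mthfs (0.98 ± 0.16), Mpeg1 (0.94 ± 0.12), RGD1306001 (0.89 ± 0.14), Dcps (0.61 ± 0.09), Cnot8 (0.39 ± 0.06) and Cyp2d1. Cyp2d1 had no counts in FRL vehicle and 1.31 ± 0.459 CPM in the FSL line. The count was 47 by DESeq2 and 15 by limma-voom, and 3, 4 and 9 without FRL vehicle 1, 2 and 3. It was 10, 11 and 9 without non-responder 1, 2 and 3, 11 and 12 without responder 2 and 3, 9 with a replicate block, 3 with a choroid plexus covariate and 3 without the libraries low in granule neuron markers.

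The myelin gene Mbp stood at 2375 ± 495 CPM in FRL vehicle, 1879 ± 439 in FSL vehicle, 3479 ± 1098 in non-responders and 2957 ± 1040 in responders (mean ± SD, n = 3).

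Line fold changes and those of responders against FSL vehicle ran opposite across genes. Their covariance was 3.63 times the value that the spread of the shared FSL vehicle libraries gives. This ratio does not decide whether shared libraries are the whole cause. Genes move together within libraries (the first principal component held 36.4% of variance), so 3 libraries give few independent draws. The fold changes and the spread were also computed on unlike scales, edgeR and log2 CPM. Were the cause a larger share of meningeal and vascular tissue in FSL vehicle, each gene's slope on meningeal markers within the other 3 groups would give its sign. This held for 65.8% of genes at an unadjusted p under 0.05 in the line comparison, against 55.4% of all genes, and for 62.7% of those in responders, with median predicted over observed sizes of 0.166 and 0.180, which leaves it open. A line difference reversed in responders predicts opposite fold changes in comparisons that share no library. Line fold changes correlated at -0.630 across genes with those of responders against non-responders. Over 20 labellings of the LAC libraries, which hold each split with both signs, the real labels gave -0.613 and the lowest other -0.492. Only 1 labelling, the real one, was as low, but 1 of 20 is the smallest share that relabelling can give, so it does not decide. The correlation also does not separate a reversal from tissue share, since responders had the lowest mean of meningeal markers. A reversal therefore stays a hypothesis.

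By the correlation bound used here FSL vehicle and non-responders are also paired by number, although the labels name no pairing. Libraries that vary together in this way would give a negative correlation of that kind with no change at all. Number 1 of both groups was also alike in choroid plexus markers (5.71 and 6.51 log2 CPM) and in meningeal markers (3.76 and 3.57). A pairing and a like tissue makeup therefore cannot be told apart. The covariance was -0.131, or 4.66 times what like-numbered libraries of the 4 groups give, and 2.72 times the value of the number that gives most. Here too genes move together within libraries and the scales differ, so these ratios do not decide whether pairing is the whole cause.

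For the 19 genes, other tissue in some libraries would shrink the fold changes once 3 marker covariates are fitted, yet the median ratio of sizes was 0.955 and all 19 kept their sign. Calls fell from 19 to 2 there, as the median SE went from 0.189 to 0.274 and the residual degrees of freedom from 8 to 5. The 19 were selected for differing across FSL-line libraries of unlike marker levels, which disfavours genes that follow these markers. The ratio is therefore no independent test. Prelp, which passed in the line comparison but is not among the 19, fell in that comparison from 2.20 to 1.13 with these covariates. A variant of 1 line against the reference might remove all counts of a gene in that line or only lower them. Of the 19 genes 1, Cyp2d1, had no counts in FRL vehicle. A partial loss cannot be seen in this way, so the number of genes without counts decides nothing without reads. If alleles of the lines act on adjacent genes, these would differ too, and 7 of 36 tested neighbours of 18 placed genes in the order of GRCr8 had an unadjusted p under 0.05, such as Clu (0.30 ± 0.09) and Cd1d1 (0.82 ± 0.32). Over 10000 random sets the mean was 2.41 and 0.98% held as many, so linked alleles stay open as a hypothesis.

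Other groupings of the same libraries were counted for each comparison. For the genes called, 1 of 10 groupings reached the real count for FSL vehicle against FRL vehicle (8; highest other 0), for responders against FRL vehicle (10; 0) and for non-responders against FRL vehicle (5; 0). The smallest share that 10 groupings can give is 1 of 10. Each other grouping also mixes the 2 lines, which adds line differences to the spread within groups, so these counts do not decide. A real count of 0 is reached by any grouping, so it decides nothing: 10 of 10 reached it for responders against FSL vehicle (highest other 3), for non-responders against FSL vehicle (5) and for responders against non-responders (0), and 84 of 84 for pooled LAC. The highest other grouping for pooled LAC called 170. It set apart FSL vehicle 2 and 3 and non-responder 2, which points to a structure of the samples beyond treatment. For the 9 FSL-line libraries 4 of 100 groupings called at least 19 genes. The highest called 266 with the same 3 libraries set apart, which points to a structure of the samples beyond the line. These 3 were the highest in meningeal markers (6.13, 7.73 and 5.62 log2 CPM, next non-responder 3 at 5.52). For pooled LAC, setting apart the 3 libraries high in choroid plexus markers called 63.

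For lists, taken over the 33 of each comparison, 5 of 10 groupings called at least the 9 of FSL vehicle against FRL vehicle (highest other 12). It was 1 of 10 for the 13 of responders against FSL vehicle (12), and 4 of 10 for the 8 of non-responders against FSL vehicle (11). Of those 10, 4 part all 3 same-number pairs, and the other 3 called at most 6 lists and 0 genes, against up to 11 and 5 in the 6 that keep a pair together. For pooled LAC 13 of 84 groupings called at least 11, the highest 13.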
